A study of Nasonia vitripennis with 9 samples.

How the data were processed

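RNA sequencing libraries were made from pools of 5 male *Nasonia vitripennis*, a parasitoid wasp, of the laboratory strain AsymCX. Larvae in the second instar, about 3 days after egg laying, were injected with double-stranded RNA against green fluorescent protein (dsGFP) at 4 µg/µl in water with red food dye, injected with water and dye, or not injected. Injected pools were collected 5 to 6 days after injection, per the labels' protocols. The larvae to be injected were placed on 1% agarose. The labels give no separate age at collection for the uninjected pools and do not say whether those larvae were handled on agarose. The labels name the stage as white pupae in one field and as whole larvae in another; the treatment protocol gives white pupae, and that word is used here. Each of the 3 groups had 3 libraries, and the labels put every library in its group. The labels do not say whether the pools of a group came from separate hosts or cultures, so p-values measure only the spread between these pools, part of which may be technical.

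Poly(A)-enriched RNA was sequenced as paired reads of 150 bp, per the labels' protocols, which describe no step that marks strand. The authors deposited 1 file per library with counts of read pairs per gene in the layout of STAR, and STAR 2.6.1b is named in the submitters' processing notes. The genome build is not given in the sources used here, so no coordinates are printed. Each file holds 4 summary lines (unmapped, multimapped, outside genes, ambiguous) and 15430 rows with 3 columns of deposited counts. The first column counts without regard to strand and was used for every main result. The other columns count by strand, and the first of them held 49.95 to 50.13% of the strand-specific counts in each library, so the counts carry no strand. Without strand, reads of overlapping antisense genes cannot be told apart, and multimapped reads were not counted, so members of near-identical gene families may be undercounted.

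Of the 15430 rows, 12 carried a fragment of a product description in place of a gene name and were left out (0.0518 to 0.0608% of counts). The other 15418 rows were matched by symbol to a table of RefSeq genes of assembly Nvit_psr_1.1, used for names and gene types only; 14940 matched and 478 did not. Most rows (14496) are named only by a locus number. Gene totals per library ranged from 33885222 to 46080606. A gene at 0 counts in a library could be present at up to 3 counts, which corresponds to 0.0651 to 0.0885 CPM; such limits cover counting error only.

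Genes were kept by edgeR's filterByExpr by group (minimum count 10, minimum total 15), which left 11665 genes. Counts were scaled by TMM factors and tested with edgeR 4.0.16 (glmQLFit with robust estimation, glmQLFTest) in R 4.3.3. All 9 libraries entered a single fit with 3 groups. Pairwise contrasts compared dsGFP with water, water with uninjected and dsGFP with uninjected, and an F test asked for any difference among the 3 groups. A second fit compared the 6 injected with the 3 uninjected libraries. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. For dsGFP against water, genes whose whole 95% confidence interval lay within 2-fold were also counted. CPM values use the TMM-scaled library sizes, and a log2 fold change is the fitted one. The summed CPM of rRNA genes per library and the limits for genes at 0 counts use unscaled gene totals instead. Library similarity was described by principal components of the 500 most variable genes.

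The 20 gene lists planned before the data were examined relied on product descriptions, which the name table does not hold. In their place 21 lists were built from gene symbols, after the symbols were seen and before any counts were compared. The 16 lists with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation 0.01, log2 CPM with prior count 2), and also with an estimated correlation and with fry. Core RNA interference genes were to be named in each comparison; by symbol alone none of dicer, argonaute-2, R2D2 or SID1 was matched, and Tudor-sn stands as the only gene of the small RNA list.

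Named genes followed a rule set before the data were examined. Among called protein-coding genes with an informative name and no overlap in CPM between groups, the 12 largest rises and the 12 largest falls were named. Where 5 or fewer genes were called, all were named with the 5 of smallest p. Up to 4 members of smallest p could serve as examples of each list. Of these examples the text gives a selection that was made after their values were seen.

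The fits were tested on simulated data, drawn from the real means, library sizes and dispersions with 200 changed genes in each of 5 runs per comparison. For dsGFP against water (11581 genes tested), 16.2% of genes changed 1.5-fold, 67.4% of those changed 2-fold and 92.7% of those changed 4-fold were called. Of all calls in these runs 5.65% were false, and the 95% intervals held the true value for 95.2% of the genes changed 2-fold. For dsGFP against uninjected (11586 genes) 63.9% of the 2-fold changes were called, and for water against uninjected (11577 genes) 63.2%. For injected against uninjected (11579 genes) the share was 73.8%. For dsGFP against uninjected, the respiration list of 66 genes lowered by 1.25-fold was called in 4 of 4 runs on 11665 genes, and 0 of 60 tests of other lists passed. The simulation draws genes independently, which real libraries do not do.

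Alternatives planned before the data were examined were RLE and upper-quartile factors, no filter, a minimum of 1 CPM in 3 libraries, the replicate number as a block, each library left out, each strand column, DESeq2 1.42.0, limma-voom, an adjusted p under 0.1, and fits of only the groups compared. For single named genes 13 of these were run: RLE factors, the block, no filter, DESeq2 and each of the 9 omissions. Other alternatives were chosen after seeing the data: thinning all libraries to the smallest total, cuticle genes as a covariate, rRNA genes left out, uninjected 2 and 3 left out together, and a term for, or omission of, 3 libraries that stood apart. Samples of 1 group differed by far more than sampling noise (chi-square per degree of freedom 94.8 to 327 over 9 pairs within groups), so none was treated as a repeat. Figures were drawn with matplotlib 3.10.9.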

Results

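Whole male wasps of *Nasonia vitripennis* were profiled by RNA sequencing to ask whether injection of dsGFP, a double-stranded RNA with no intended target in the wasp and a common control in RNA interference experiments, changes gene expression. The 3 groups were dsGFP-injected, water-injected and uninjected, with 3 pools of 5 individuals each. Gene totals were 34754342 ± 1093928 (SD, n = 3) in the dsGFP libraries, 36729166 ± 487110 (SD, n = 3) in the water libraries and 42464193 ± 3644501 (SD, n = 3) in the uninjected libraries. Every injected library was shallower than every uninjected library.

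Libraries correlated at r = 0.96 to 0.99 within groups and 0.94 to 0.99 between groups (log2 CPM across genes, which are not independent replicates). The first principal component held 48.9% of the variance of the 500 most variable genes, and the second 30.3%. Neither component separated all 3 groups. On the second, the water libraries (-12.5 to -9.90) lay below the uninjected libraries (-4.73 to 46.2). The dsGFP libraries (-14.4 to 5.07) overlapped both. Uninjected 3 lay at 47.4 on the first component, against -24.8 and -26.3 for dsGFP 1 and dsGFP 2, and uninjected 2 lay at 46.2 on the second, where every other library was at or below 5.07.

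The comparison of dsGFP with water holds the injection constant and varies the dsRNA. By edgeR's test 0 genes were called higher or lower in dsGFP-injected than in water-injected pupae, and DESeq2 called 6. Tudor-sn, a nuclease of the RNA-induced silencing complex, was at 252 ± 32.2 CPM with dsGFP and 246 ± 35.9 CPM with water (SD, n = 3 each; log2 fold change 0.04, SE 0.16). The 5 genes with the smallest p were protein-coding genes named only by a locus number, and none passed edgeR's test (adjusted p = 0.702 each). LOC100680022 had 1.41 CPM with dsGFP and 0.395 CPM with water, and LOC103316975 had 1.87 and 3.76 CPM. LOC100116571 had 12.5 and 19.5 CPM, LOC103315967 had 12.7 and 18.8 CPM, and LOC100118424 had 86.1 and 61.6 CPM.

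With edgeR's quasi-likelihood test, 0 of 11665 genes passed, and 710 had an unadjusted p under 0.05, where 583 would be met by chance. Limma-voom also called 0 genes, and DESeq2 called 6, of which 3 were higher and 3 lower with dsGFP. Among those called by DESeq2 were LOC100680022, LOC100116571, LOC103315967, LOC103316975 and the serine protease gene SP49. For 9688 genes (83.1%) the whole 95% confidence interval of the fold change lay within 2-fold, and for 7497 (64.3%) within 1.5-fold. The median half-width of these unadjusted intervals was 0.33 on the log2 scale.

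As groups, 4 of 16 tested lists passed between dsGFP and water, although edgeR called 0 of their members and DESeq2 called SP49. Nervous system genes were lower in 18 of 21 members (median log2 fold change -0.30, adjusted p = 3.89e-04 by camera). Their examples were the glutamate-gated chloride channel GluCl (-0.42, SE 0.17) and the acetylcholine receptor subunit nAChRa1 (-0.40, SE 0.17). Odorant receptors were lower in 52 of 78 (median -0.19, adjusted p = 5.09e-04). Or139 had 0.247 CPM with dsGFP and 0.570 CPM with water, and Or168 had 0.479 and 1.15 CPM. These levels are low, with 6 to 13 counts of Or139 and 6 to 25 of Or168 in each dsGFP library. The lists were not tested on thinned libraries. Genes of mitochondrial respiration were lower in 58 of 66 (median -0.09, adjusted p = 0.00258), among them the cytochrome c oxidase subunits Cox7a1 (-0.64, SE 0.17) and Cox6c (-0.35, SE 0.15). Serine proteases and their homologs were higher in 25 of 34 (median 0.11, adjusted p = 0.0418), with SP49 at 4.55 and 0.559 CPM and SP102 at 11.4 and 6.88 CPM. With an estimated correlation none of the 4 passed: adjusted p = 0.640 for nervous system, odorant receptors and serine proteases and adjusted p = 0.800 for respiration. Without dsGFP 2 only nervous system and serine protease genes passed, without water 3 only nervous system genes and odorant receptors, and the serine protease call was also lost without dsGFP 1, dsGFP 3 or water 2.

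The other tested lists did not pass in this comparison. In 2 of 16 other settings the cuticle and chitin list passed by camera, and in 2 of 16 the recombination, repair and germ line list (lowest adjusted p = 0.0314 each). Immune and melanisation genes were higher in 5 of 7 members (adjusted p = 0.369), cytochrome P450 genes in 19 of 34 (adjusted p = 0.478) and cuticle and chitin genes in 25 of 38 (adjusted p = 0.369). Other detoxification genes were higher in 10 of 27 (adjusted p = 0.672), gustatory receptors in 5 of 8 (adjusted p = 0.478) and the yellow and royal jelly-like family in 7 of 13 (adjusted p = 0.419). Cell cycle genes were higher in 12 of 16 (adjusted p = 0.478), recombination, repair and germ line genes in 14 of 18 (adjusted p = 0.108) and hormones and neuropeptides in 4 of 8 (adjusted p = 0.869). Storage proteins were higher in 3 of 5 (adjusted p = 0.369), translation genes in 4 of 10 (adjusted p = 0.827) and dynein and dynactin genes in 5 of 11 (adjusted p = 0.672). For other detoxification genes the median (-0.019) and the test pointed down and the mean (0.011) up. The lists too small to test were muscle, chaperones, sex determination, the small RNA pathway and microRNA precursors, and they held 0 called genes in this comparison.

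**Figure D1:**
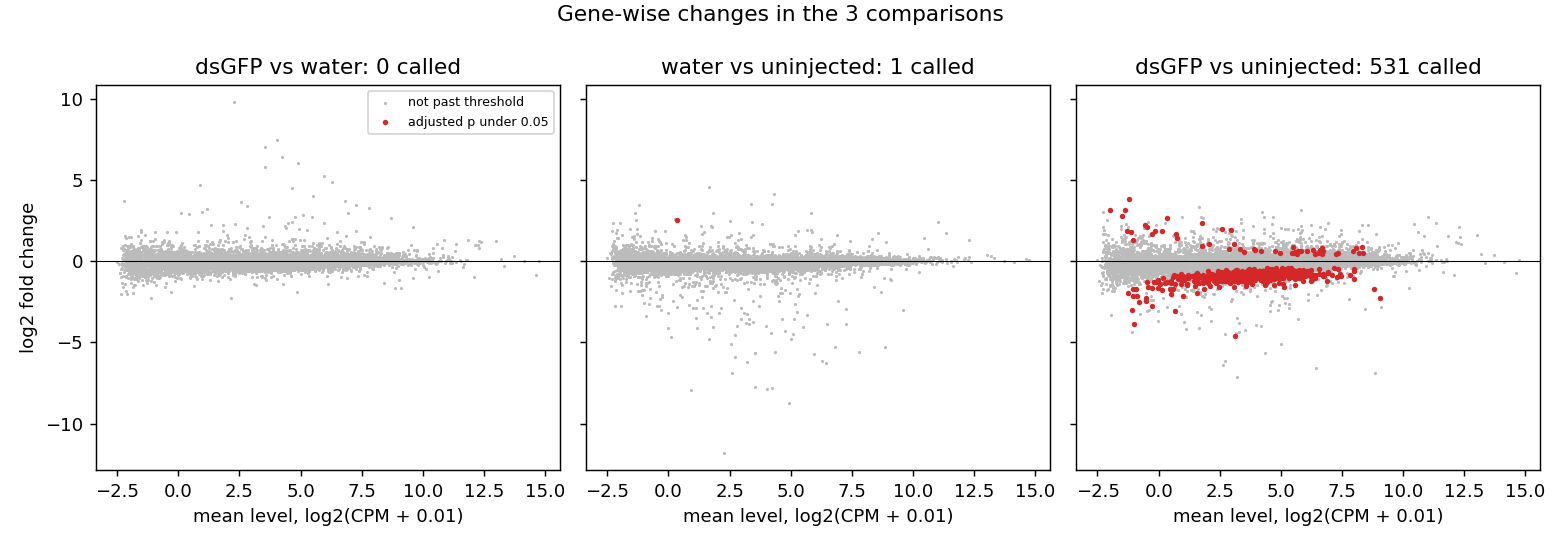
Log2 fold change against mean level (log2 of CPM + 0.01) for each of 11665 genes in the 3 comparisons; red points passed an adjusted p of 0.05. There were 0 red points for dsGFP against water, 1 for water against uninjected and 531 for dsGFP against uninjected.

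The comparison of water with uninjected pupae addresses the injection together with its dye and handling. A single gene rose with water injection, LOC116416025, a protein-coding gene named only by a locus number. Its level went from 0.283 ± 0.0331 to 1.67 ± 0.109 CPM (SD, n = 3 each). The log2 fold change was 2.55 (SE 0.22, edgeR adjusted p = 0.00247). This gene had 12 to 13 counts in each uninjected library and 54 to 67 in each water library. It did not pass with the second strand column, with uninjected 2 and 3 both left out, or with dsGFP 1, water 3 and uninjected 3 all left out. The next genes by p did not pass. LOC100122048 had 0.0437 CPM uninjected and 0.540 CPM with water, and LOC116416113 had 0.0631 and 0.501 CPM. LOC100122593 had 44.5 CPM uninjected and 26.7 CPM with water, and LOC100120201 had 14.7 and 5.74 CPM.

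Among genes of known families, CYP314A1, which encodes the enzyme that makes 20-hydroxyecdysone, the active moulting hormone, had 77.3 ± 32.7 CPM uninjected and 37.5 ± 6.68 CPM with water (SD, n = 3 each; edgeR adjusted p = 0.555). Zasp66, a Z-disc protein of muscle, had 19.3 and 8.86 CPM (edgeR adjusted p = 0.475). The cuticular protein gene CPR44 had 3.21 and 1.09 CPM, and the P450 gene CYP4AB12 had 86.0 and 109 CPM. Tudor-sn differed by 0.01 on the log2 scale (SE 0.16). In all, 662 genes had an unadjusted p under 0.05, limma-voom called 1 gene and DESeq2 called 46.

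Of the lists, only mitochondrial respiration passed between water and uninjected pupae, lower in 50 of 66 members (median -0.09, camera adjusted p = 0.0140; adjusted p = 0.960 with an estimated correlation). Its examples were Cox6c, at 11.6 CPM with water and 16.4 CPM uninjected, and the complex I subunit Ndufab1, at 122 and 149 CPM. Nervous system genes were lower in 19 of 21 (adjusted p = 0.0569), with GRD, a ligand-gated ion channel subunit, at 16.4 and 23.2 CPM. The other 14 lists had adjusted p of 0.806 or more; median, mean and test differed in sign for gustatory receptors, cytochrome P450, other detoxification, recombination and repair, translation, and dynein genes. Leaving out uninjected 1 raised the count of called genes from 1 to 7, and leaving out water 1 left 0 lists. Adjusted over the list alone, 1 cuticle and 1 muscle gene fell. Without uninjected 3 the nervous system list passed and the respiration list did not, its direction turning up (adjusted p = 0.780), and without dsGFP 3, water 2 or uninjected 1 both passed.

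Between dsGFP-injected and uninjected pupae 531 genes differed, 51 higher and 480 lower with dsGFP. The median called rise was 0.76 and the median called fall -0.92 on the log2 scale, and 194 genes changed at least 2-fold (20 up, 174 down). The named genes that rose were the P450 genes CYP6AQ5 (420 ± 129 against 226 ± 38.1 CPM), CYP4AB12 (117 ± 3.32 against 86.0 ± 8.43 CPM) and CYP6CK7 (95.1 ± 5.58 against 71.2 ± 6.03 CPM; SD, n = 3 each). P450 enzymes oxidise hormones and foreign compounds. Genes named only by a locus number, which are most rows, were left out of naming in this comparison. The named rises and falls therefore do not show which families changed most. Of the 34 P450 genes tested 3 rose and 2 fell, CYP314A1 from 77.3 ± 32.7 to 28.4 ± 3.81 CPM and CYP4AB21 from 15.8 to 10.1 CPM, and the list did not pass as a whole (camera adjusted p = 0.859).

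Genes of the cuticle and of the respiratory chain were among the named falls. CPR44 fell from 3.21 ± 1.28 to 0.380 ± 0.0518 CPM (log2 fold change -3.07, SE 0.40, edgeR adjusted p = 0.00871). CPR22 fell from 0.829 to 0.189 CPM, at 5 to 7 counts in each dsGFP library, and CPR47 fell from 9.16 to 4.72 CPM. The cuticle list as a whole did not pass (26 of 38 higher, median 0.72, adjusted p = 0.429), so these 3 fell while most members had higher values, and CPR49 did not pass, at 29.5 against 42.7 CPM. Of 3 muscle genes, too few to test as a list, Zasp66 fell from 19.3 ± 6.63 to 7.24 ± 1.39 CPM (log2 fold change -1.41, SE 0.24, edgeR adjusted p = 0.0111), and the tropomyosin genes did not pass, with Tm2 at 22.8 against 50.1 CPM and Tm1 at 846 against 754 CPM. Cox7a1 fell from 16.9 ± 1.68 to 8.48 ± 1.37 CPM (log2 fold change -0.998, SE 0.17, edgeR adjusted p = 0.0106) and Cox6c from 16.4 ± 2.55 to 9.10 ± 1.14 CPM. The remaining named falls included the odorant receptors Or140 (0.776 to 0.234 CPM, at 4 to 13 counts in each dsGFP library) and Or41 (2.05 to 0.871 CPM). The others were GRD (23.2 to 13.5 CPM), the dynein light chain gene TctexA (10.6 to 6.01 CPM) and Gnbp1-2, of a family that binds microbial glucans (20.3 to 12.7 CPM). Tudor-sn did not differ detectably (log2 fold change 0.05, SE 0.16).

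**Figure D2:**
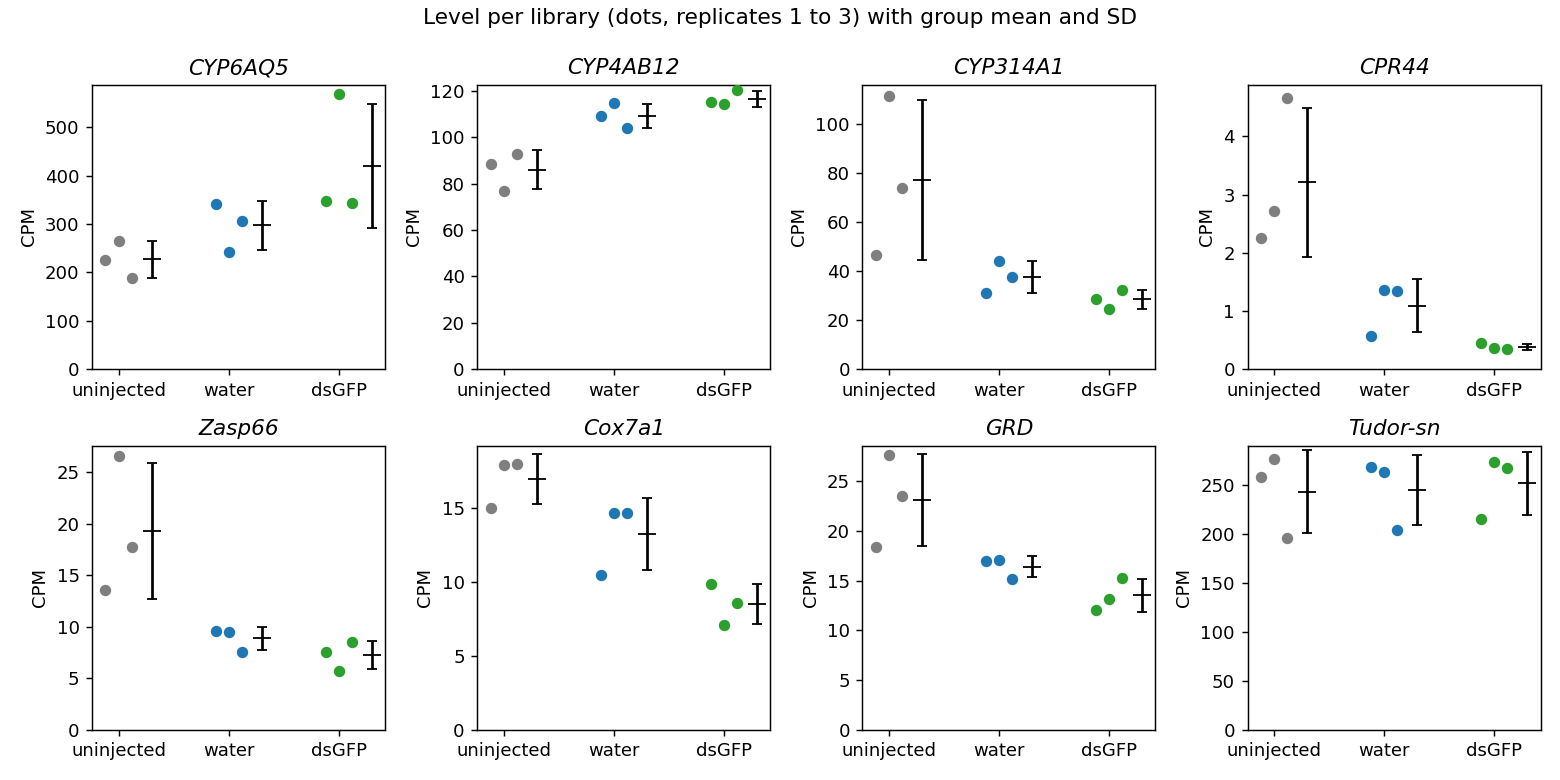
Level in CPM of 8 named genes in each library (dots, replicates 1 to 3 from left to right) with the group mean and SD (black). CPR44 sat at 3.21 CPM on average in uninjected, 1.09 in water and 0.380 in dsGFP libraries, and Tudor-sn overlapped in all 3 groups.

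Between dsGFP and uninjected pupae 3 lists passed, each downward. Respiration genes were lower in 64 of 66 members (median -0.16, camera adjusted p = 8.78e-05), with 2 called. Nervous system genes were lower in 18 of 21 (median -0.37, adjusted p = 9.17e-05), with GRD called over all genes and 5 genes adjusted over the list alone; the examples that did not pass over all genes were the potassium channel Slo at 29.5 against 42.2 CPM, GluCl at 23.4 against 34.8 CPM and nAChRa4 at 6.41 against 10.2 CPM. Odorant receptors were lower in 53 of 78 (median -0.27, adjusted p = 0.00423), with 2 called. With an estimated correlation each had an adjusted p = 0.981. Within each group the same library, dsGFP 1, water 3 or uninjected 3, had the lowest mean of the nervous system list (log2 CPM 2.98, 3.29 and 3.35) and the highest of the respiration list (6.60, 6.67 and 6.85). Without dsGFP 2 the odorant receptors did not pass, and without uninjected 3 cell cycle and repair genes also passed, upward, for 5 lists. Serine proteases were higher in 22 of 34 and did not pass (adjusted p = 0.0844), but passed upward in 5 of 16 other settings, among them without dsGFP 2, water 2 or uninjected 1 and with upper-quartile factors (lowest adjusted p = 0.0188). Immune and melanisation genes were higher in 3 of 7 (adjusted p = 0.859), with test direction up and median (-0.11) and mean (-0.25) down, and the other lists had adjusted p of 0.234 or more. Of these, hormones and neuropeptides held 1 called fall, CYP314A1, and dynein genes 1, TctexA. Counts adjusted over the list alone were 2 rises and 1 fall for hormones and neuropeptides, 3 rises and 3 falls for P450 genes, and 4 falls for cuticle genes. They were 2 falls each for respiration and muscle genes, 1 each for immune genes, dynein genes and microRNA precursors, and 0 for odorant receptors. Median, mean and test also differed in sign for gustatory receptors, cytochrome P450, the yellow family, hormones and neuropeptides, and dynein genes.

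Of the 51 genes that rose, 5 were annotated as rRNA, out of 12 rRNA genes tested, with log2 fold changes of 1.30 to 2.36; this class was singled out after the calls were seen, and all 12 had higher values with dsGFP. The injected libraries carried 29.7 ± 8.51 CPM on rRNA genes (SD, n = 6) and the uninjected libraries 9.56 ± 3.54 CPM (SD, n = 3). With the rRNA genes left out 525 genes were called.

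The count of 531 depended on which pools were used, and without uninjected 1 it rose to 681. It was 134 without dsGFP 2, 244 without dsGFP 1 and 295 without uninjected 2, and 5 with uninjected 2 and 3 both left out, of which 0 were among the 531; that fit keeps a single uninjected library, assumed to vary like the other groups. With dsGFP 1, water 3 and uninjected 3 all left out it was 0, in a fit with only 2 libraries per group. Other omissions of 1 library per group were not run. The 0 can therefore not be set apart from the loss of libraries as such. With all libraries DESeq2 called 939 and limma-voom 425. In the 13 alternatives run for single genes CYP4AB12 lost the call in 7, CYP6CK7 in 9 and CYP6AQ5 in 10. Of the named falls, CYP4AB21 lost it in 9, CPR22 in 8, Or140 in 7, Gnbp1-2 in 6, CYP314A1 and CPR47 in 5 each, TctexA in 4, GRD and Or41 in 3 each, Zasp66 and Cox6c in 1 each, and CPR44 and Cox7a1 in 0. With the cuticle list as a covariate, a fit chosen after the calls were seen, CYP314A1, CPR22, Or140 and CYP4AB21 did not pass. Their log2 fold changes were -1.37, -2.13, -1.41 and -0.61 there, against -1.45, -2.12, -1.70 and -0.64 without the covariate. With only the list's uncalled genes as the covariate these 4 (CYP314A1 at -1.34, adjusted p = 0.126) did not pass. Nor did CYP6AQ5 (0.66, adjusted p = 0.0770), CYP6CK7, Or41, TctexA and Gnbp1-2. Of these, CYP6CK7 had a larger fold change than without it (0.448 against 0.419) and the others smaller ones. With dsGFP 1, water 3 and uninjected 3 marked by a term CYP6AQ5 (adjusted p = 0.0654), CYP314A1 (adjusted p = 0.0575) and CPR22 did not pass. Their log2 fold changes were 0.889, -1.446 and -2.10 with the term against 0.890, -1.446 and -2.12 without it. The term marks 1 library in each group, so it could hardly move a fold change between groups. That these values stayed alike is therefore no evidence that the genes are free of the split.

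The dsGFP and water groups share the uninjected libraries, so their fold changes against them move together by chance. Across genes the fold changes correlated at r = 0.727 with a covariance of 0.190. With unchanged groups simulated 50 times r was 0.494 on average (0.446 to 0.529) and the covariance 0.0461 (0.0410 to 0.0541), and the difference in covariance was 0.144. The sign was shared by 79.7% of genes, against 66.5% in the simulations. The 480 genes that fell with dsGFP had a median of -0.46 in water against uninjected and of -0.46 in dsGFP against water; they were chosen on libraries that both share, so these medians are not independent evidence. The overlap of calls was 1 gene, LOC116416025, against 0.00437 for independent lists and 0.04 on average in the simulations. The simulations called only 0.42 and 0.4 genes on average, so their overlap is no match for lists of 531 and 1. The 3 control libraries cannot be parted into sets of at least 2, and part of the excess may come from the shared controls. The simulations gave each gene the same spread in all groups and drew genes independently. In the data uninjected 3 and uninjected 2 lay farthest out on the first and second principal components. A wider spread of the shared controls would raise r and the covariance, so the simulations cannot size the excess. In the direct test of dsGFP against water edgeR called 0 genes and DESeq2 called 6, so the larger count against uninjected pupae does not by itself measure a difference between the treatments.

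Injected pupae of both kinds were then set against uninjected pupae, 6 libraries against 3, and 4 genes passed. LOC116416025 was higher with injection (1.74 ± 0.144 CPM, n = 6, against 0.283 ± 0.0331 CPM, n = 3; log2 fold change 2.62, SE 0.20, edgeR adjusted p = 4.20e-04), in 6 of 6 injected libraries. LOC100122048 was higher, at 0.612 against 0.0437 CPM, with 15 to 35 counts in each injected and 1 to 4 in each uninjected library. LOC100120201 was lower, at 5.32 against 14.7 CPM, and LOC100117489 was lower, at 0.212 against 1.28 CPM. LOC100122593, next by p, had 23.7 against 44.5 CPM and did not pass (edgeR adjusted p = 0.0561). Leaving out uninjected 1 raised the count to 97, leaving out uninjected 2 gave 2, and leaving out any dsGFP library, water 1, water 3 or uninjected 3 gave 1. LOC116416025 passed in each of the 13 alternatives run for single genes, while LOC100122048 and LOC100120201 lost the call in 9 each and LOC100117489 in 10, and 0 genes passed with the second strand column, and 0 rose with uninjected 2 and 3 both left out. DESeq2 called 445 genes.

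A test for any difference among the 3 groups called 238 genes. Leaving out single libraries gave 0 to 384: 0 without uninjected 2 or uninjected 3, 384 without uninjected 1, 2 without water 1 and 1 without any of the other 5. Limma-voom called 1 gene and DESeq2 called 682.

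**Figure D3:**
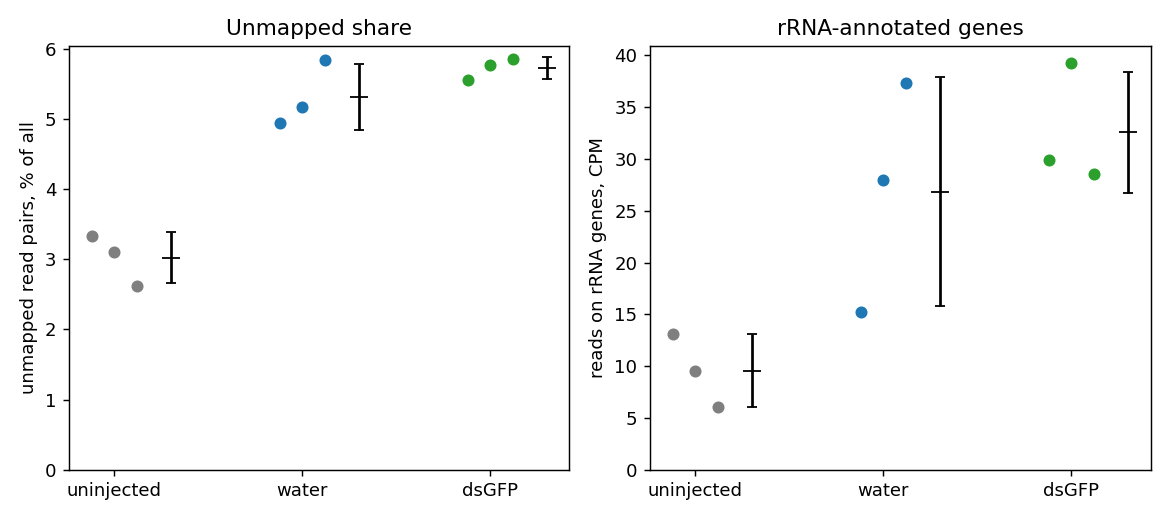
Share of read pairs left unmapped (percent of all pairs) and reads on rRNA-annotated genes (CPM) in each library (dots) with the group mean and SD (black). Every injected library lay between 4.94% and 5.86% unmapped, above the 2.63% to 3.34% of the uninjected libraries.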

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

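The tests in this part were all chosen after the result was seen. The read pairs that could not be placed lie outside the gene counts and were a larger share of every injected library than of every uninjected library. They made up 5.52 ± 0.385% of all pairs in the injected libraries (SD, n = 6) and 3.02 ± 0.362% in the uninjected libraries (SD, n = 3), a difference of 2.50 points. Multimapped pairs were 0.822% against 0.730%, also without overlap. These measures were singled out because the libraries did not overlap, so a permutation test on the same libraries would only restate that.

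Reads of the injected dsRNA were a possible source of the unmapped pairs. The water libraries received none and held 84.8% of the excess of the dsGFP libraries, each lying above every uninjected library, which argues against dsRNA reads as the whole source. The dsGFP libraries exceeded the water libraries by 0.411 points (exact permutation test, two-sided p = 0.3; 3 against 3 cannot go below 0.1). Carry-over of ribosomal RNA may contribute: among the 6 injected libraries unmapped share and rRNA gene CPM correlated at r = 0.821 (exact permutation p = 0.0444) and Spearman's rho 0.60 (exact permutation p = 0.242), but without water 1 and dsGFP 2, the farthest from the median, r was 0.536, so the relation rests on those samples and stays open. That both coefficients had to pass was decided after they were seen.

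The second pattern is the larger count for dsGFP against uninjected. Depth is argued against, because 534 genes were called after thinning every library to the smallest total. The stage of the pools as read by cuticle genes is argued against as the whole cause, because the fallen genes kept a median of -0.87 (quartiles -1.02 and -0.72) against -0.92 when the cuticle list was a covariate, and 409 of 480 falls and 38 of 51 rises passed. With a covariate of the uncalled cuticle genes the median was -0.86, and 363 of 480 falls and 28 of 51 rises passed. Other differences in developmental timing stay open and untested. An effect of dsGFP itself stays open; its direct test against water called 0 genes by edgeR and 6 by DESeq2. The 10 splits of 3 against 3 are too few for a share under 0.05; 1 of 10 gave as many genes, the real one, and the highest other gave 0.

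The third pattern is a structure among the libraries. Of the 84 splits of 9 libraries into 3 and 6, the one that set dsGFP 1, water 3 and uninjected 3 apart called 1754 genes, against 10 for the next. Of these genes 1134 were lower and 620 higher in the 3 libraries, 1746 by less than 2-fold. Gene totals of 4 of the other 6 libraries lay within the range of the 3. For the cuticle score the number was also 4. For gene totals this count decides nothing. The 3 come from all groups, and every injected library was shallower than every uninjected library. Within groups, the 3 libraries had the lowest gene total in 1 group and the highest in 0, and likewise for the cuticle score. Exact permutation tests within groups gave two-sided p = 0.815 for gene totals and p = 0.593 for the cuticle score. With 27 choices they cannot exclude either cause. A shared library batch could be the source and stays open, since the labels name no batch. The 3 libraries, 1 from each group, had the highest share of pairs outside genes in 3 of 3 groups, by 0.778 points on average (exact permutation test within groups, two-sided p = 0.0370, the smallest that 27 choices can give; adjusted p = 0.111 over 9 measures), and also the highest ambiguous and multimapped shares and TMM factor. Depth, RNA quality, gene length and stage stay open too.

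Other splits were counted for the remaining results. For injected against uninjected 3 of 84 splits gave as many genes as the real 4, a share under 0.05. The others among these gave 1754 and 10 genes and mixed injected with uninjected libraries. The share therefore does not set injection apart from other structure among the libraries. For any difference 1 of 100 drawn of 280 partitions gave as many as the real 238, and the highest other gave 1. Chance in how the libraries fell into groups is thus unlikely there but not excluded. Not all partitions were drawn, and the count was 0 without uninjected 2. For the rest the 10 splits are too few for a share under 0.05. In these, dsGFP against water had 0 genes and a highest other of 0 (10 of 10 as large). It had 9688 genes within 2-fold and a highest other of 9974 (10 of 10), and 4 lists and a highest other of 5 (4 of 10). Water against uninjected had 1 gene and a highest other of 0 (1 of 10) and 1 list and a highest other of 5 (9 of 10). For dsGFP against uninjected there were 3 lists and a highest other of 5 (6 of 10). In each comparison other splits of the same libraries thus reached or exceeded the number of passing lists, so these numbers do not set the real groups apart.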

How the results depend on the processing

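Covariate, thinned, rRNA, split and paired-omission fits were chosen after seeing the data. Of 217 alternative values of the counts, 145 stayed within 1.5 times the reported one; for the others, except where fewer libraries explain it, the cause was not tested. Of 273 alternative values of the 21 called named changes, 167 kept the call, 106 lost it and 0 changed sign. For each of these genes the groups compared did not overlap in CPM. A change of sign was therefore hardly possible, and the 0 is no evidence on direction. With 3 pools per group many true changes in single genes can be missed. In the simulations of dsGFP against water 16.2% of 1.5-fold and 67.4% of 2-fold changes were called.

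Injected against uninjected (4 genes) gave 1 gene with RLE factors, 9 with upper-quartile factors, 10 with no filter, 1 with a 1 CPM minimum, 2 with the first strand column, 0 with the second, 2 with limma-voom, 445 with DESeq2, 131 at an adjusted p under 0.1, and 1 each when thinned, with either cuticle covariate or with the split as a term. Any difference (238) gave 149 with the second strand column, 682 with DESeq2, 1 with limma-voom, 441 at 0.1, 154 with the cuticle covariate of uncalled members and 1 with the split term. For dsGFP against uninjected (531), counts were 939 with DESeq2, 852 with the split term (248 higher, 604 lower), 801 at 0.1 and 255 with only those groups. The split was picked from these data for having the most calls, so its term takes out spread chosen for its size. The 852 may be inflated by that choice. Water against uninjected (1) gave 46 with DESeq2 and 0 with the second strand column, and dsGFP against water (0) gave 6 with DESeq2. With only the 6 libraries outside the split, 2 per group, all 5 tests called 0 genes. Without uninjected 2 and 3 the counts were 9 for water against uninjected, 5 for dsGFP against uninjected and 7 for any difference. Lists: the estimated correlation and fry left 0 in each comparison, and water against uninjected had 2 with upper-quartile factors, the second strand column or the split term.

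With single libraries left out, genes called ranged from 0 to 0 for dsGFP against water, 1 to 7 for water against uninjected, 134 to 681 for dsGFP against uninjected, 0 to 384 for any difference and 1 to 97 for injected against uninjected. Genes within 2-fold ranged from 9151 to 9776, and lists from 2 to 5, 0 to 2 and 3 to 5 in the order of the report. The log2 fold change of Tudor-sn, which passed in 0 of these fits, changed sign. For dsGFP against water it was -0.025 without dsGFP 2, -0.00635 without dsGFP 3 and -0.0838 without water 3, and at most 0.142. For water against uninjected it was -0.063 without water 1, -0.0548 without water 2 and -0.138 without uninjected 3, and at most 0.124. For dsGFP against uninjected it was -0.0124 without dsGFP 2 and -0.0993 without uninjected 3, and at most 0.143.

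The replicate numbers do not pair the libraries: 2 of 9 same-number pairs deviated together at over 0.1 (r from -0.330 to 0.428), and 1 of 9 libraries correlated best with its own number. With the replicate block 539 genes were called for dsGFP against uninjected, 216 for any difference, 1 for injected against uninjected, 1 for water against uninjected and 0 for dsGFP against water, with 2 lists for water against uninjected.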

Other observations

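Several cuticle genes differed widely between pools. CPLCP1 ranged from 9.05 CPM in uninjected 3 to 6551 CPM in dsGFP 2, and CPLCP2 from 15.8 CPM to 14605 CPM in the same libraries. CPR59 ranged from 2.82 CPM in uninjected 3 to 932 CPM in water 1, and CPR37 from 5.71 CPM in uninjected 3 to 860 CPM in dsGFP 2. The mean log2 CPM of the cuticle list was 3.67 ± 0.631 with dsGFP, 3.36 ± 0.801 with water and 3.00 ± 1.02 uninjected (SD, n = 3 each). These genes were chosen after their values were seen.

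Uninjected 2 held the highest values of several genes, also chosen after their values were seen. The defensin genes Def1-1 and Def1-2 were at 602 and 822 CPM there, and the next highest libraries had 71.7 and 196 CPM. The Osiris family genes Osi7 and Osi8 were at 51.7 and 75.6 CPM, against at most 1.15 and 2.31 CPM elsewhere. A set of 6 protein-coding genes had at least 5 CPM in uninjected 2, dsGFP 1 and dsGFP 3 and at most 0.809 CPM in the other 6 libraries. Of these, LOC107981201 had 234, 28.2 and 8.11 CPM in those 3 libraries, and LOC100462678 had 83.0, 51.2 and 11.95 CPM. The ratio of dsGFP 1 to uninjected 2 ran from 0.121 to 0.941 across the 6 genes.

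The 3 libraries that formed the split of 1754 genes differed from the other 6 in the following genes, chosen from the calls of that split after they were seen. Tudor-sn was at 205 ± 9.74 CPM in dsGFP 1, water 3 and uninjected 3 and at 268 ± 6.51 CPM in the other 6 (SD). The translation factor gene EF-1a was at 2599 and 3257 CPM, the chaperonin gene Cct7 at 191 and 237 CPM, and the ATP synthase genes Atp5a1 and Atp5b at 538 and 684 CPM and at 447 and 594 CPM. Cox5b went the other way, at 254 and 215 CPM. So did the mean of the whole respiration list, which within each group was highest in dsGFP 1, water 3 and uninjected 3 (log2 CPM 6.60, 6.67 and 6.85). The median level of the 1134 lower genes was 99.5 CPM, that of the 620 higher genes 44.6 CPM and that of all tested genes 28.2 CPM.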
